A study of Rattus norvegicus with 12 samples.

How the data were processed

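Gene expression was measured on whole-transcript Affymetrix rat gene arrays in cultures of ventricular cardiomyocytes from newborn Wistar rats. The 12 arrays formed 4 groups of 3: untreated cultures (control), and cultures given adenovirus carrying mef2Cγ+ (γ+ group), mef2Cγ- (γ- group) or mef2Cγ+23/24 (23/24 group). Groups were taken from the sample titles, and the labels number the arrays of each group as biological replicates 1 to 3 without saying whether these were separate cell isolations, so p-values measured the spread between these samples. The labels name no culture or labelling batch. The cells were plated for 44 h and kept without serum for 24 h, and 2 µg of total RNA was labelled per array, per the labels.

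The values used were the deposited values, taken as log2, 1 table for all arrays. The submitters' processing notes name MAS5 with no version. The values ran from 1.09 to 13.89 with array medians of 5.33 to 5.53, the range of log2 intensities and not of linear MAS5 signals. The background correction, the summarization, the log base and the normalization are not given in the sources used here. Exactly equal values on a pair of arrays were counted to see how the arrays had been normalized. Such values occurred in all 21 pairs within the control and 23/24 arrays together, within the γ+ arrays, or within the γ- arrays (27 to 111 per pair), and in 0 of the 45 pairs across these sets. The arrays therefore appear to have been normalized in 3 separate runs, and among the 6 comparisons the 23/24 group against control is the one made within a run. All other differences were set across runs.

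The table held 28826 probe sets. A probe table gave 1 gene symbol for 15209 of them, several for 306 and none for 13311. Symbols were brought up to date through the Entrez identifiers in the RefSeq table of the GRCr8 assembly, which held 15178 of those of the single-gene probe sets. No genome coordinates were used. Probe sets with a mean over the 12 arrays at or below the 40th percentile (log2 4.78) were left out, which kept 17295. The single-gene probe set with the highest mean stood for each gene, giving 10025 genes. No probe set carried the symbol Mef2c, so Mef2c and the transgenes were not analysed here.

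Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with a mean for each group over all 12 arrays, which left 8 residual degrees of freedom. Benjamini-Hochberg adjustment was made within each comparison, and genes with an adjusted p under 0.05 were called. A moderated F test asked whether any group differed. Each of 22 gene lists was tested in each of the 6 comparisons with limma's camera at a preset correlation of 0.01, adjusted over the 132 tests together, and again with an estimated correlation. The lists covered the sarcomere, fetal and hypertrophic genes, calcium handling and ion channels, oxidative phosphorylation, fatty acid oxidation, glycolysis, cell cycle G1/S and G2/M, p53 and apoptosis, the unfolded protein and other stress responses, autophagy and atrophy, cardiac transcription factors, MEF2 targets, atrial markers, extracellular matrix and fibroblast genes, smooth muscle, endothelial and macrophage or leukocyte markers, the interferon response, NF-κB inflammation, cholesterol and lipid synthesis, and the skeletal muscle program. Some genes were on more than 1 list. On simulated data built on these arrays, the procedure called 24% of genes changed by 0.25 log2, 94% of those changed by 0.5 and 100% of those changed by 1 or 2 (50 genes each); 16 of its 175 calls were false, and it called 0 genes in simulated unchanged γ- and 23/24 groups. The raised list was found there, and 0 of 20 unchanged lists passed. The simulated genes were drawn independently and without offsets between runs. False calls from correlated genes or from separate normalization were therefore not tested.

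The groups, comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. That rule took the MEF2 family; the 10 largest rises and falls per comparison (4 and 4 for the γ- group against the 23/24 group) among called genes whose 3 arrays per group did not overlap, passing over placeholder symbols; up to 3 genes of lowest adjusted p per list with at least 2 called members; and Nppa, Nppb, Myh6, Myh7, Acta1 and Atp2a2. Where nothing passed, the 3 genes of lowest p were given. The placeholder rule was extended to that last case after LOC366310 was seen there (23/24 group against control: log2 fold change -0.51, adjusted p = 0.209 by limma). Alternatives were median centring and quantile normalization of the arrays, no filter and a filter at the 60th percentile, the mean over a gene's probe sets, other variance priors, array weights, replicate number as a block, the 6 compared arrays alone, a fold minimum of 1 log2, and leaving out each array of the groups compared. The alternatives added later are named with the sensitivity results. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.081.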

Results

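The data asked how forms of the transcription factor MEF2C change gene expression in cultured neonatal rat ventricular cardiomyocytes. MEF2C binds promoters of muscle genes, and its γ segment, which alternative splicing includes or leaves out, is known as a repressor domain. Cultures received adenovirus for the form with the segment (γ+), the form without it (γ-), or a γ+ variant that the labels name 23/24 without defining it, and untreated cultures served as control. Each group had 3 arrays, and 10025 genes were tested. The standard deviation of the difference between arrays of a group was 0.216 to 0.272 in the control, 0.200 to 0.293 in the γ+ group, 0.220 to 0.236 in the γ- group and 0.203 to 0.253 in the 23/24 group, in log2 units. No virus without an insert was among the groups, so each comparison with control includes any effect of adenovirus.

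The first comparison asked what the γ+ form did relative to untreated cells. Genes of the contractile cardiomyocyte were lower in the γ+ cultures. Xirp2, an actin-binding protein of the intercalated disc, fell by 3.54 ± 0.06 log2 (SE, n = 3 per group) from a level of 10.97 in the control. Csrp3, the muscle LIM protein of the Z-disc, fell from a log2 level of 12.27 ± 0.02 in the control to 9.28 ± 0.04 in the γ+ group (SD, n = 3 each). Nppb, which encodes brain natriuretic peptide, fell from 13.04 ± 0.00 to 10.29 ± 0.17. In the other direction, Ccne2, the cyclin E2 of S-phase entry, rose from 6.71 ± 0.08 to 9.71 ± 0.07. The antiviral interferon-induced gene Rsad2 rose by 2.74 ± 0.09 log2 (SE) from a level of 6.80. For these genes all 3 γ+ arrays lay on one side of all 3 control arrays, and the limma adjusted p was 3.1e-16 for Xirp2, 3.7e-17 for Csrp3, 7.4e-15 for Nppb and Ccne2, and 4.7e-13 for Rsad2.

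**Figure D1:**
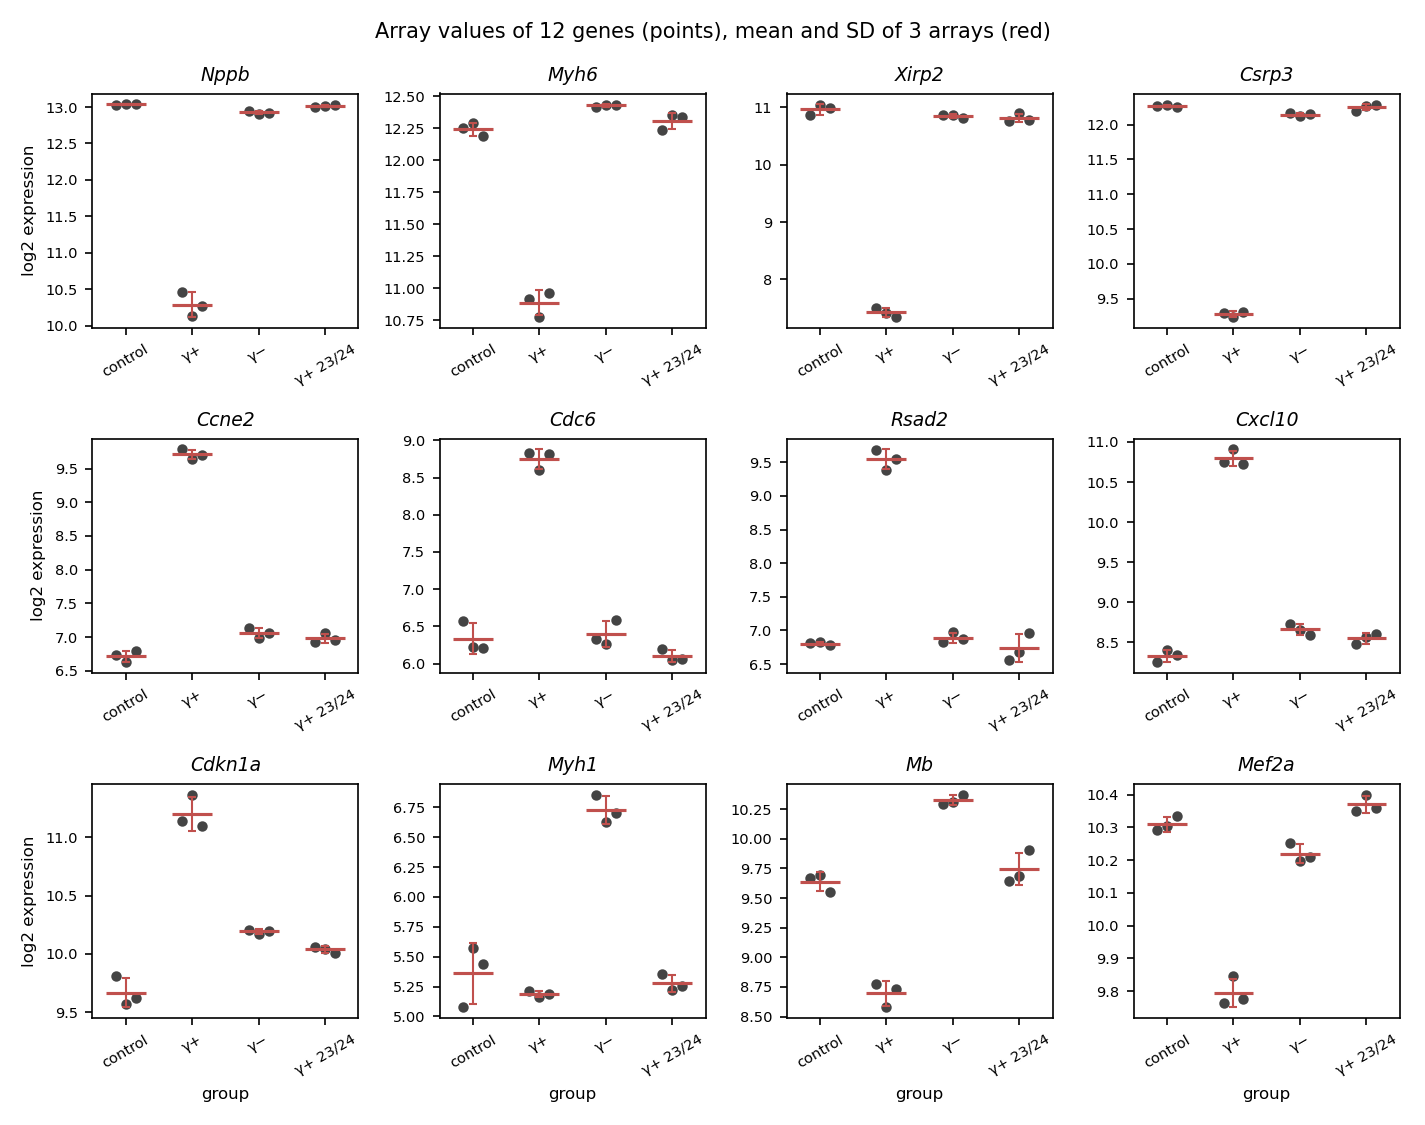
Log2 expression of 12 genes (vertical axes) on each array of the 4 groups (horizontal axes); points are arrays, red lines the mean and bars the SD of 3 arrays. In the first 8 panels and for Cdkn1a and Mef2a the γ+ arrays stood apart from those of the other groups. Csrp3 was at 9.28 against 12.27 in the control, while Myh1 was highest in the γ- arrays (6.73 against 5.36 in the control). The γ+ and γ- levels were set across normalization runs.

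All 28 measured sarcomere genes fell in the γ+ group (28 of 28 also when adjusted over the list alone), with a median log2 fold change of -1.21. Tnni3, the cardiac troponin I, changed by -2.16 ± 0.06 (SE, n = 3 per group), Myom1, the M-band protein myomesin, by -1.99 ± 0.05, Myh6 by -1.35 ± 0.05, Myh7 by -1.54 ± 0.08 and Acta1 by -1.08 ± 0.05. Myh6 and Myh7 are close paralogs, which the probe sets may not fully separate. The list of fetal and hypertrophic genes had 15 of 20 members lower and 2 higher (15 and 2 adjusted over the list alone, median -1.03). Nppa, which encodes atrial natriuretic peptide, fell by 0.52 ± 0.05 against 2.75 ± 0.06 for Nppb, and Rcan1, a calcineurin regulator, changed by -2.21 ± 0.05. The 2 higher members, named after their values were seen, were Hmox1 (0.20) and Mt1 (0.29). Of the 35 tested genes on the MEF2 target list, 30 fell and 1 rose (30 and 2 adjusted over the list alone, median -0.94). The riser was Bop1, a ribosome biogenesis gene named after its value was seen. Whether Bop1 is a MEF2 target was not checked here. Of 32 calcium handling and ion channel genes, 25 fell and 2 rose (25 and 2 adjusted over the list alone, median -0.86). Ryr2, the calcium release channel, changed by -1.89 ± 0.05, Atp1b1 by -1.72 ± 0.04, Kcnq1 by -2.02 ± 0.07 and the calcium pump Atp2a2 by -1.15 ± 0.06, whereas Kcnd2 (1.69) and Fkbp1b (0.29), named after their values were seen, rose. In limma's camera the adjusted p was 1.6e-15 for the sarcomere and 1.4e-06 for the fetal and hypertrophic list. It was 1.7e-10 for the MEF2 targets and 1.3e-06 for the calcium and ion channel list. With an estimated correlation all 4 calls held narrowly, at a camera adjusted p of 0.0482, 0.0482, 0.0426 and 0.0454 in that order.

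Genes of energy metabolism were lower as well. Of 46 oxidative phosphorylation genes, 45 fell (45 lower and 1 higher adjusted over the list alone), with a median of -0.67. Cox6a2, a muscle subunit of cytochrome oxidase, fell from 12.31 to 11.47. The camera adjusted p from limma was 4.8e-12, with an adjusted p = 0.146 with an estimated correlation. Of 32 fatty acid oxidation genes, 24 fell and 1, Hadh, rose (26 and 1 adjusted over the list alone, median -0.42). Cpt1b, the mitochondrial carnitine transferase, changed by -1.62 ± 0.07 and Ppara by -1.56 ± 0.07. The limma camera adjusted p was 1.9e-05, and the adjusted p = 0.101 with an estimated correlation. Of 26 glycolysis genes, 22 fell and 3 rose, Pdk1, Pfkfb1 and Pfkl (22 and 3 adjusted over the list alone, median -0.34, limma camera adjusted p = 0.0014, adjusted p = 0.400 with an estimated correlation). Eno3, the muscle enolase, changed by -1.81 and Hk1 by -1.03. Cholesterol and lipid synthesis had 19 of 20 genes lower (19 adjusted over the list alone, median -0.61, limma camera adjusted p = 8.0e-06, adjusted p = 0.0910 with an estimated correlation), with Scd at -1.36. The atrial markers had 12 of 15 genes lower and 1, Fgf12 (0.57), higher (12 and 1 adjusted over the list alone, median -0.61, limma camera adjusted p = 0.0013, adjusted p = 0.0677 with an estimated correlation), among them Sln, which encodes sarcolipin, at -2.86 and Bmp10 at -3.03. Of 19 genes of the skeletal muscle program, 12 fell (12 adjusted over the list alone, median -0.25, limma camera adjusted p = 0.0104, adjusted p = 0.0720 with an estimated correlation), with Ckm at -1.90. Under median centring and under quantile normalization 7 of them fell. Hadh, Pdk1, Pfkfb1, Pfkl and Fgf12 were named after their values were seen.

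Cell cycle and interferon genes rose. All 49 measured G2/M genes rose (49 adjusted over the list alone, median 1.21). Ccnb2 rose by 1.41 ± 0.06, Tpx2 by 1.33 ± 0.05 and Plk4 by 1.68 ± 0.07. Of 42 G1/S genes, 38 rose and 3 fell (38 and 3 adjusted over the list alone, median 1.35). Cdc6, which licenses replication origins, rose by 2.41 ± 0.11, Ccne1 by 2.15 ± 0.07 and the helicase subunit Mcm5 by 2.04 ± 0.07. The 3 that fell, named after their values were seen, were the D-type cyclins Ccnd1 (-2.06) and Ccnd2 (-1.24) and their partner kinase Cdk6 (-0.97). Of 44 interferon response genes, 41 rose and 2, Nmi and Samd9l (named after their values were seen), fell (41 and 2 adjusted over the list alone, median 1.01). Under median centring and under quantile normalization 1 gene of the list was lower. Herc6 rose by 2.88 ± 0.08, the chemokine Cxcl10 by 2.46 ± 0.06 and Oasl by 2.27 ± 0.06. Camera in limma gave an adjusted p of 1.1e-26 for G2/M, 7.6e-18 for G1/S and 3.2e-18 for the interferon list. With an estimated correlation the 3 calls held narrowly, at a camera adjusted p of 0.0454, 0.0482 and 0.0426. The p53 and apoptosis list had 17 genes higher and 7 lower of 31 (17 and 7 adjusted over the list alone, median 0.22, limma camera adjusted p = 0.0080, adjusted p = 0.0901 with an estimated correlation). Its members Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, and Cdkn1c, which encodes p57, rose by 1.54 ± 0.07 and 1.52 ± 0.07.

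Markers of other cell types also fell. Extracellular matrix and fibroblast genes had 37 of 39 lower and 1, Fbln1 (0.32, named after its value was seen), higher (37 and 1 adjusted over the list alone, median -1.08), with Lox at -1.98 ± 0.05 and Col1a1 at -1.69 ± 0.04. Of 15 smooth muscle genes, 14 fell (14 adjusted over the list alone, median -0.95), with Cnn1 at -1.82 ± 0.06. In the same way 18 of 18 endothelial genes fell (18 adjusted over the list alone, median -0.75), with Aqp1 at -1.79 ± 0.07. The limma camera adjusted p was 1.2e-15, 7.6e-07 and 4.3e-06 for these 3 lists. With an estimated correlation each held narrowly, at 0.0426, 0.0426 and 0.0454. Of 16 macrophage or leukocyte genes 12 fell (13 adjusted over the list alone, median -0.38, limma camera adjusted p = 0.0245, adjusted p = 0.0830 with an estimated correlation), among them Cd14 at -0.73; with the filter at the 60th percentile this list no longer passed (0.0615).

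The remaining lists did not pass as a whole in the γ+ group against control. NF-κB inflammation had 18 genes lower and 6 higher of 31 (19 and 6 adjusted over the list alone, median -0.26, limma camera adjusted p = 0.0609), with Ccl7 at -1.52 and Lcn2 at -1.96. That list passed under median centring (0.0469), without a filter (0.0436), at the 60th percentile (7.5e-04), with array weights (0.0399), and without control replicate 1 (0.0478) or γ+ replicate 2 (0.0318). Cardiac transcription factors had 11 lower and 5 higher of 25 (11 and 5 adjusted over the list alone, median -0.11, 0.429), with Smyd1 at -1.98, Myocd at -1.39 and Tbx20 at -0.66. The 5 higher genes, named after their values were seen, were Gata6, Hey2, Mef2b, Nfatc3 and Yap1. Mef2b rose to 5.725 from a control level of 4.789, which is close to the filter cutoff of 4.782. Autophagy and atrophy had 17 lower and 7 higher of 32 (17 and 7 adjusted over the list alone, median -0.26, 0.106), with Trim55 at -1.69. The stress list had 8 lower and 8 higher of 28 (8 and 7 adjusted over the list alone, median 0.03, 0.648), with its median and mean of opposite sign and Hspb1 at -1.92. Within the MEF2 family Mef2a changed by -0.52 ± 0.05, Mef2d by -0.62 ± 0.13 and Mef2b by 0.94 ± 0.13, with limma adjusted p of 4.8e-08, 4.6e-04 and 9.9e-06. Mef2d was uneven among the γ+ arrays, with an SD of 0.40 there against 0.07 in the control. Standard errors pool the spread of all 4 groups, so this SD also widens those of Mef2d in the other comparisons.

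By limma, 6509 of the 10025 genes (64.9%) differed between the γ+ group and control, 2631 higher and 3878 lower, and 907 of them changed by at least 1 log2 (311 higher, 596 lower). Among all genes, 66.6% had γ+ arrays that did not overlap the control arrays, where chance gives 10%. Of the 22 lists 18 passed, 4 upward and 14 downward, and 10 held with an estimated correlation. The γ+ and control arrays appear to come from separate normalization runs, and 3577 of the calls also exceeded the 99th percentile of the γ- changes at the same intensity, a limit chosen after seeing the data. Median centring raised the share of higher genes among the calls from 40.4% to 51.2%.

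**Figure D2:**
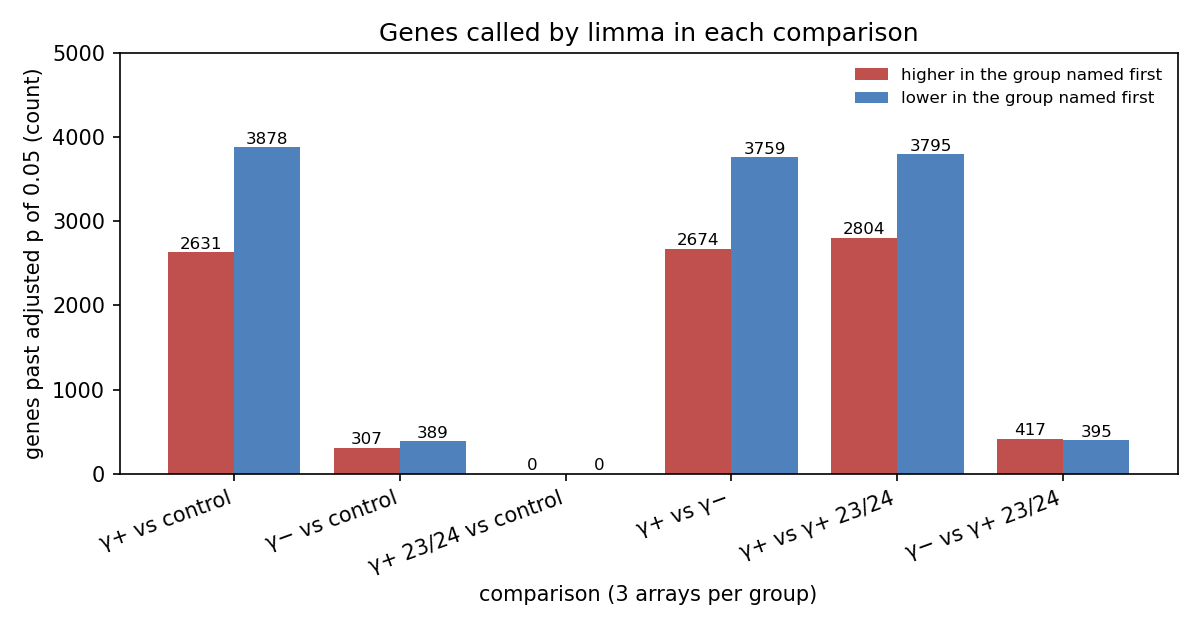
Genes past a limma adjusted p of 0.05 in each of the 6 comparisons (horizontal axis), as counts (vertical axis) of genes higher (red) and lower (blue) in the group named first; 3 arrays per group, 10025 genes. The 3 comparisons with the γ+ group hold 6433 to 6599 genes each, the others 0 to 812; all except the 23/24 group against control were made across normalization runs.

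The second comparison set the γ- group against control. Myosin heavy chain genes of skeletal muscle rose there: Myh1 from 5.36 ± 0.26 to 6.73 ± 0.12 (SD, n = 3 each), Myh2 by 0.95 ± 0.10 and Myh3 by 0.59 ± 0.08 on the log2 scale. These paralogs are nearly identical in sequence, and the probe sets may not separate them. Mb, which encodes the oxygen-binding myoglobin, rose by 0.69 ± 0.07, Fgf12 by 0.72 ± 0.08, and Gria1, an AMPA receptor subunit, by 0.95 ± 0.12. The largest falls were in Mettl27 (-1.03 ± 0.16), Galntl6 (-0.89 ± 0.13) and B3galt1 (-0.77 ± 0.15). In all of these the 3 γ- arrays lay on one side of the 3 control arrays, with limma adjusted p from 7.2e-06 (Myh1) to 0.0077 (B3galt1). Each kept an adjusted p under 0.05 when the arrays were rescaled or left out singly, but with a minimum change of 1 log2 only Myh1 and Mettl27 remained, and at the 60th percentile Mb was the one of these genes still tested.

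The interferon list shifted upward in the γ- group, with 11 of 44 genes higher and 0 lower (19 and 1 adjusted over the list alone). Its median was 0.20, with a limma camera adjusted p of 3.1e-10, and of 0.0482 with an estimated correlation. Oas1b rose by 0.66 ± 0.10, Ifit1 by 0.60 ± 0.08 and Eif2ak2, the RNA-activated kinase PKR, by 0.37 ± 0.06. Cdkn1a rose by 0.53 ± 0.07 and Ccne2 by 0.35 ± 0.07, while Tk1 changed by -0.36 ± 0.07 and Cdca3 by -0.48 ± 0.09. NF-κB inflammation had 6 genes lower and 1, Vcam1, higher of 31 (8 and 2 adjusted over the list alone), among them Ccl7 (-0.46 ± 0.06), Cxcl1 (-0.46 ± 0.07) and Ptgs2 (-0.36 ± 0.07). Under median centring 3 were lower. The list did not pass as a whole (limma camera adjusted p = 0.116), though it did with the filter at the 60th percentile (5.6e-04). Extracellular matrix and fibroblast genes were lower (median -0.10), with 4 of 39 called, Loxl1, Pdgfrb, Col3a1 and Mfap4 (10 lower and 1 higher adjusted over the list alone, limma camera adjusted p = 7.3e-04, adjusted p = 0.242 with an estimated correlation). Under median centring 1 was called, with Pdgfrb and Col3a1 among those lost, and under quantile normalization 5 were. Col3a1 was also lost at the 60th percentile, without the intensity trend and with the replicate block. The skeletal muscle program had 3 of 19 genes higher, the myosins, and 1, Mybpc2, lower (4 and 2 adjusted over the list alone, median 0.11, limma camera adjusted p = 0.0062, adjusted p = 0.0600 with an estimated correlation). This list did not pass without a filter (0.116) or at the 60th percentile (0.450). No list of other cell type markers besides the matrix genes passed. Smooth muscle had a median of 0.04 with 0 of 15 called, also adjusted over the list alone (limma camera adjusted p = 0.462). The endothelial list had a median of -0.11, with Sox18 (-0.52 ± 0.11), Tek (-0.34 ± 0.09) and Tie1 lower and Flt1 higher of 18 (3 and 1 adjusted over the list alone, limma camera adjusted p = 0.107). The macrophage or leukocyte list also had a median of -0.11, with Laptm5 (-0.46 ± 0.08), C1qb and Cd53 lower of 16 (5 adjusted over the list alone, limma camera adjusted p = 0.198). Under median centring 1 endothelial and 2 macrophage or leukocyte genes were lower. Vcam1, Mfap4, Tie1 and Mybpc2 were named after their values were seen.

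Fetal and hypertrophic genes had a median of -0.10 in the γ- group, with Myc (-0.35 ± 0.06) and Rcan1 (-0.18 ± 0.05) lower of 20 (3 lower adjusted over the list alone, limma camera adjusted p = 0.0071, adjusted p = 0.182 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.04 with Ndufa2 and Uqcrh higher of 46 (0 adjusted over the list alone, limma camera adjusted p = 0.0072, adjusted p = 0.624 with an estimated correlation). Fatty acid oxidation genes also had a median of 0.04, with Mlycd and Ppargc1a, the mitochondrial coactivator, higher and Cd36 and Ech1 lower of 32 (4 and 2 adjusted over the list alone, limma camera adjusted p = 0.0269, and 0.0516 without control replicate 2, adjusted p = 0.386 with an estimated correlation). Cd36 was named after its value was seen. Under median centring Rcan1, Ndufa2, Uqcrh, Cd36 and Ech1 lost their calls, and Mlycd and Ppargc1a lost theirs in 5 of the 12 runs leaving out an array. Of the genes always reported, Myh6 rose by 0.19 ± 0.05 (limma adjusted p = 0.0427), a call that 4 of the 12 runs leaving out an array kept. Nppa (-0.04 ± 0.05), Nppb (-0.11 ± 0.06), Myh7 (-0.04 ± 0.08), Acta1 (-0.09 ± 0.05), Atp2a2 (0.04 ± 0.06), Mef2a (-0.09 ± 0.05), Mef2b (0.02 ± 0.13) and Mef2d (0.08 ± 0.13) were not called, though Nppb and Acta1 were without γ+ replicate 2. The pooled error of Mef2d carries its wide γ+ spread, while its SD was 0.04 in the γ- group and 0.07 in the control.

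By limma, 696 genes (6.9%) differed between the γ- group and control, 307 higher and 389 lower, with 2 of them, Myh1 and Mettl27, by at least 1 log2. The balance turned with the scaling: 228 were higher and 208 lower under median centring, and 399 and 385 under quantile normalization. The groups did not overlap in 33.4% of genes, where chance gives 10%. The γ- and control arrays appear to come from separate normalization runs. The count was 313, 332 and 343 without control replicate 1, 2 or 3, 275, 267 and 284 without γ- replicate 1, 2 or 3, and 1665 without γ+ replicate 2, which enters through the shared spread alone.

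The 23/24 group against control was the comparison within a normalization run. No gene was called by limma. Of the tested genes, 899 had an unadjusted p under 0.05, and the lowest adjusted p was 0.209. The 3 genes of lowest p were Oasl (0.35 ± 0.06 log2, SE, n = 3 per group), Cdkn1a (0.37 ± 0.07) and Cdkl3 (-0.45 ± 0.09), each with a limma adjusted p of 0.209, and in each of them the groups did not overlap. All 3 were called with array weights, and Oasl under quantile normalization. Nppa differed by 0.01 ± 0.05, Nppb by -0.02 ± 0.06, Myh6 by 0.07 ± 0.05, Myh7 by 0.01 ± 0.08, Acta1 by 0.08 ± 0.05, Atp2a2 by 0.00 ± 0.06, Mef2a by 0.06 ± 0.05, Mef2b by 0.20 ± 0.13 and Mef2d by -0.03 ± 0.13. The pooled error of Mef2d again carries its γ+ spread, while its SD in the 23/24 group was 0.02.

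As a set, interferon genes were shifted upward in the 23/24 group by a median of 0.07, with 0 of 44 called and 6 adjusted over the list alone (limma camera adjusted p = 1.6e-08, adjusted p = 0.0527 with an estimated correlation). The skeletal muscle program had a median of 0.07 with 0 of 19 called, also adjusted over the list alone. Its limma camera adjusted p was 0.0031, and 0.0482 with an estimated correlation. It was 0.0641 under quantile normalization, 0.343 at the 60th percentile and 0.0628 without 23/24 replicate 1. Endothelial genes had a median of -0.11 with 0 of 18 called, also adjusted over the list alone (limma camera adjusted p = 0.0193, adjusted p = 0.178 with an estimated correlation), and 0.394 at the 60th percentile, 0.102 without control replicate 1 and 0.0997 without 23/24 replicate 2. Glycolysis genes had a median of 0.03, and -0.02 under median centring, with 0 of 26 called, also adjusted over the list alone (limma camera adjusted p = 0.0488, adjusted p = 0.647 with an estimated correlation). This call was lost in several alternatives, among them without control replicate 3 (0.312) and without 23/24 replicate 3 (0.258). The groups did not overlap in 17.9% of genes, where chance gives 10%. Without γ+ replicate 2, which enters through the shared spread alone, 58 genes were called (22 higher, 36 lower), with array weights 220 were (68 higher, 152 lower), and without control replicate 2 the count was 1.

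**Figure D3:**
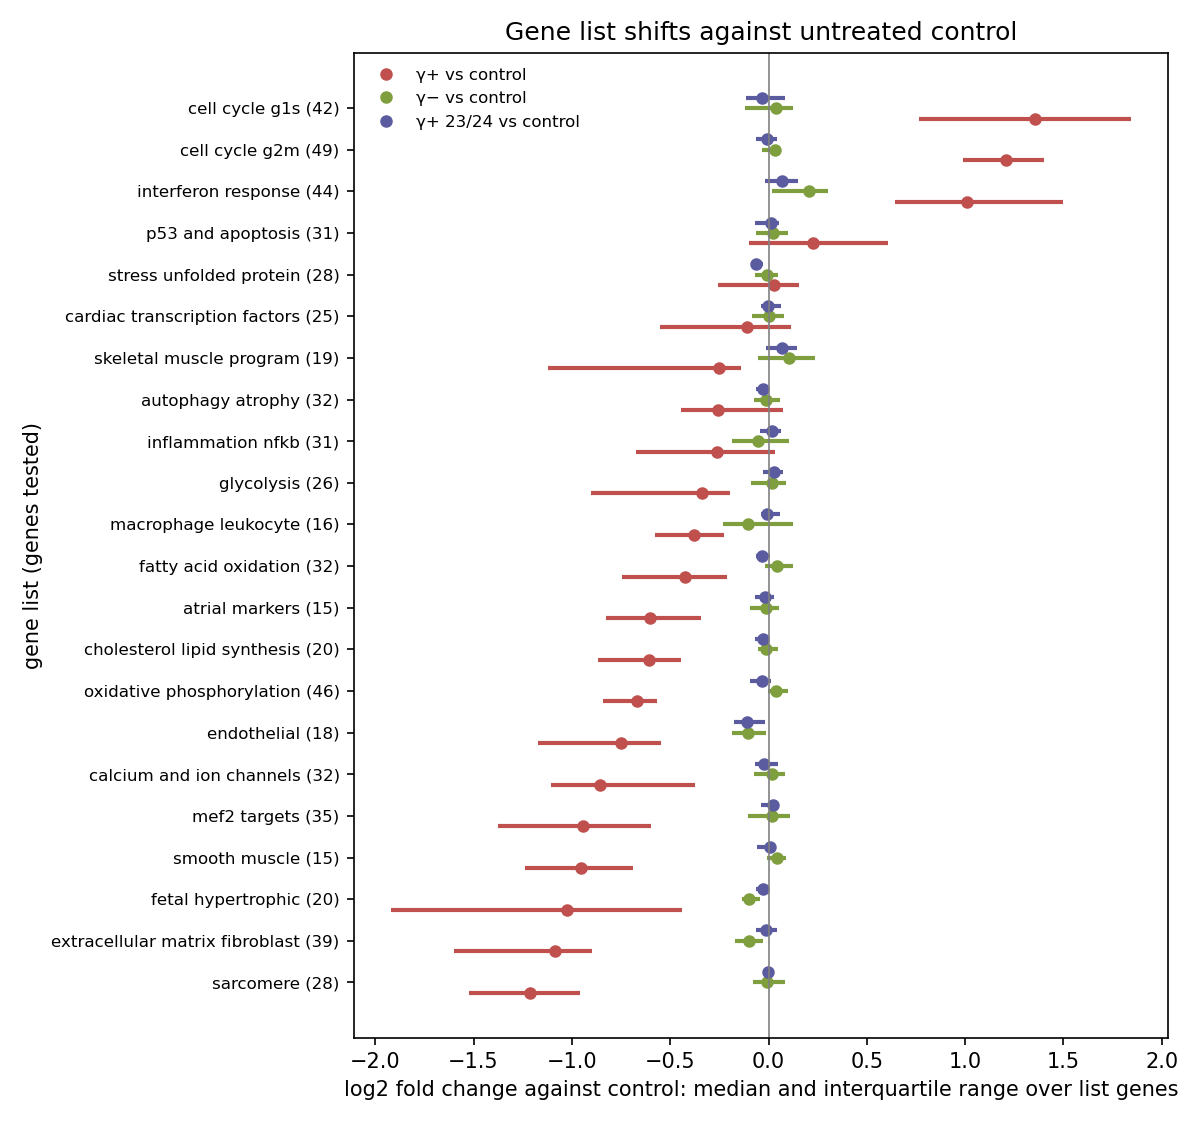
Median (points) and interquartile range (lines) of the log2 fold changes against control (horizontal axis) over the tested genes of 22 lists (vertical axis, number of genes in brackets), for the γ+ (red), γ- (green) and 23/24 (blue) groups, 3 arrays each. In the γ+ group medians ran from -1.21 (sarcomere) to 1.35 (G1/S), and in the other groups the interferon list stood at 0.20 (γ-) and 0.07 (23/24); γ+ and γ- medians were set across normalization runs.

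Setting the γ+ group against the other transduced groups asked what the γ segment and the 23/24 change do when adenovirus is present on both sides. Against the γ- group, Rsad2 (2.65 ± 0.09 log2, SE, n = 3 per group), Ccne2 (2.65 ± 0.07), Psrc1 (2.56 ± 0.08) and Herc6 (2.46 ± 0.08) were most strongly higher in the γ+ group. Xirp2 (-3.43 ± 0.06), the sodium channel subunit Scn3b (-3.17 ± 0.07), B3galt2 (-3.04 ± 0.12) and Itgb1bp2, which encodes melusin (-2.89 ± 0.06), were most strongly lower. Against the 23/24 group the values were 2.81 ± 0.09 for Rsad2, 2.73 ± 0.07 for Ccne2, 2.65 ± 0.11 for Cdc6, 2.91 ± 0.08 for Herc6, -3.39 ± 0.06 for Xirp2, -3.34 ± 0.07 for Scn3b and -2.97 ± 0.04 for Csrp3. Nppb changed by -2.64 against the γ- group and by -2.73 against the 23/24 group, Myh6 by -1.54 and -1.42, and Atp2a2 by -1.18 and -1.15. The groups did not overlap for any of these genes, and their limma adjusted p ranged from 4.1e-17 (Csrp3) to 4.5e-11 (Atp2a2), both against the 23/24 group.

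The 28 sarcomere genes were all lower in the γ+ group than in the γ- group (28 adjusted over the list alone, median -1.15) and than in the 23/24 group (28 adjusted over the list alone, median -1.24). On the MEF2 target list 30 of 35 genes were lower and 1 higher against the γ- group (median -1.05). Adjusted over the list alone these were 30 and 1. Against the 23/24 group 31 were lower and 1 higher (32 and 1 adjusted over the list alone, median -0.96). The higher list member was Bop1 in both, not checked to be a MEF2 target. G2/M genes were higher in 49 of 49 in both comparisons (49 adjusted over the list alone), with medians of 1.24 and 1.25. The 44 interferon genes had 40 higher and 1 lower against the γ- group (40 and 1 adjusted over the list alone, median 0.84) and 41 higher and 2 lower against the 23/24 group (42 and 2 adjusted over the list alone, median 0.94). Extracellular matrix and fibroblast genes were lower in 38 and 37 of 39 (38 and 38 adjusted over the list alone), with medians of -1.02 and -1.10. The limma camera adjusted p of these lists lay between 1.1e-26 and 2.0e-11 in both comparisons. With an estimated correlation all held narrowly, at camera adjusted p from 0.0426 to 0.0482. The NF-κB list passed against the 23/24 group (17 lower and 4 higher of 31, 17 and 4 adjusted over the list alone, limma camera adjusted p = 0.0267, adjusted p = 0.114 with an estimated correlation). Its 4 higher genes, named after their values were seen, were the cytokines Tnf (0.93), Ccl5 (0.83), Ccl4 (0.70) and Il6.

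By limma, 6433 genes (64.2%) differed between the γ+ and γ- groups, 2674 higher and 3759 lower in the γ+ group, and 6599 (65.8%) between the γ+ and 23/24 groups, 2804 higher and 3795 lower. Changes of at least 1 log2 numbered 868 and 902, and 3571 and 3598 of the calls exceeded the 99th percentile of the γ- changes at the same intensity. The groups did not overlap in 67.1% and 67.4% of genes, where chance gives 10%. Of the 22 lists, 17 passed against the γ- group (4 upward, 13 downward, 12 with an estimated correlation) and 19 against the 23/24 group (4 upward, 15 downward, 11 with an estimated correlation). Both comparisons were made across normalization runs. Against the γ- group 3091 genes were higher and 3059 lower under median centring. Median centring shifted the median of all genes in the comparison with the 23/24 group by 0.137 and the share of higher genes among its calls from 42.5% to 58.5%. Relative to all genes the centred list medians were -1.17 for the sarcomere, 1.01 for interferon, 1.44 for G1/S, 1.32 for G2/M and -1.02 for extracellular matrix and fibroblast genes.

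The γ- and 23/24 groups were compared last. Myh1 was higher in the γ- group by 1.45 ± 0.11 log2 (SE, n = 3 per group), Gria1 by 0.93 ± 0.12, Plppr5 by 0.87 ± 0.06 and Mb by 0.58 ± 0.07. Galntl6 (-1.04 ± 0.13), Cldn9 (-0.83 ± 0.14), Gp9 (-0.76 ± 0.13) and Cdk5r2 (-0.73 ± 0.12) were lower, with limma adjusted p from 3.0e-06 (Myh1) to 0.0032 (Gp9) and no overlap between the groups. Ppargc1a was higher by 0.50 ± 0.07, and oxidative phosphorylation had 6 of 46 genes higher, among them Ndufa2 by 0.49 ± 0.08 (6 adjusted over the list alone, median 0.09, limma camera adjusted p = 4.5e-04, adjusted p = 0.494 with an estimated correlation). Fatty acid oxidation had 4 of 32 genes higher, Ppargc1a, Pdk4 (0.37 ± 0.07), Acaa2 and Hadh (5 adjusted over the list alone, median 0.10, limma camera adjusted p = 0.0144, adjusted p = 0.335 with an estimated correlation). The interferon list was higher, with Herc6 (0.45 ± 0.08), Oas1b (0.50 ± 0.10), Eif2ak2, Ifit1 and Rtp4 up and Oasl (-0.24) down of 44 (7 and 2 adjusted over the list alone, median 0.11, limma camera adjusted p = 0.0155, and 0.0534 without 23/24 replicate 1, adjusted p = 0.359 with an estimated correlation). Extracellular matrix and fibroblast genes had 5 lower, Loxl1, Mfap4, Mmp14, Mmp2 and Pdgfrb, and 1 higher, Tgfb3, of 39 (11 and 2 adjusted over the list alone, median -0.10, limma camera adjusted p = 0.0010, adjusted p = 0.248 with an estimated correlation). NF-κB inflammation had 5 lower, Ccl7, Csf1, Cxcl1, Lcn2 and Ptgs2, and 1 higher, Vcam1, of 31 (7 and 2 adjusted over the list alone, median -0.10, limma camera adjusted p = 0.0045, adjusted p = 0.0600 with an estimated correlation). The macrophage or leukocyte list had 3 lower, Laptm5 (-0.31 ± 0.08), C1qb and Cd53, of 16 (5 adjusted over the list alone, median -0.07) and did not pass (limma camera adjusted p = 0.0629), but did under median centring (0.0344, with the median at -0.01 and the calls of all 3 genes lost), without control replicate 1 (0.0476) and without 23/24 replicate 1 (0.0458). Fetal and hypertrophic genes had 3 lower, Acta1, Mt1 and Myc, of 20 (3 adjusted over the list alone, median -0.05, and 0.02 under median centring, limma camera adjusted p = 0.0301, adjusted p = 0.282 with an estimated correlation). This list did not pass under median centring (0.132), quantile normalization (0.0726) or no filter (0.136), or without γ- replicate 1 (0.0543) or 23/24 replicate 2 (0.0546). Under median centring Acta1, Mt1, Myc, Pdgfrb, Mfap4, Ccl7 and Csf1 lost their calls. Hadh, Ifit1, Rtp4, Oasl, Loxl1, Mmp14, Mmp2, Lcn2, Ptgs2 and Vcam1 were named here after their values were seen.

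By limma, 812 genes (8.1%) differed between the γ- and 23/24 groups, 417 higher and 395 lower in the γ- group, with 2, Myh1 and Galntl6, by at least 1 log2, and no overlap between the groups in 36.2% of genes, where chance gives 10%. Mef2a was not called (-0.15 ± 0.05, limma adjusted p = 0.0521), but was under quantile normalization, without a filter, with the mean over probe sets, with array weights and without γ+ replicate 2. This comparison was made across normalization runs. The count was 263, 463 and 317 without γ- replicate 1, 2 or 3, 309, 359 and 529 without 23/24 replicate 1, 2 or 3, and 1838 without γ+ replicate 2, and under median centring the share of higher genes among the calls was 77.9% instead of 51.4%.

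Across all 4 groups the moderated F test of limma called 7045 genes (70.3%). No gene could be counted as called in the same direction in all 3 vector groups against control, because the 23/24 group had 0 calls. Without γ+ replicate 2 there were 21 and without control replicate 2 there was 1. Between the γ+ and γ- groups, 138 genes were called higher in both and 262 lower in both, where independent lists of these sizes would share 80.6 and 150.5, and 136 were called in opposite directions (220.8 for independent lists). In 50 simulations of unchanged groups that share the control arrays, the mean counts were 0, 0.02 and 0. Unchanged groups give hardly any calls, so these counts cannot show how much overlap the shared control arrays add. The covariance of the log2 fold changes of the γ+ and γ- groups was 0.0212 against 0.0039 simulated, whereas their correlation was 0.226 against 0.500 simulated. The simulated groups held noise alone, while the SD of the real changes was 0.584 for the γ+ group and 0.161 for the γ- group. The lower correlation therefore does not show that the 2 responses differ. The 3 control arrays are too few to be divided between the comparisons, so part of the overlap may come from them.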

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

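The limit at the 99th percentile of the γ- changes, and the runs leaving out an array of a group not compared, were chosen after seeing the data. Among the 382 gene results named and the 132 list tests, no called gene or list passed in the opposite direction in any alternative. Named genes were not followed under the fold minimum, which many of them do not reach, or from 6 arrays alone. In the other alternatives, where tested, the genes named by the rule kept their calls in the γ+ comparisons. For the γ- group, 24 of them lost their call against control and 28 against the 23/24 group in at least 1 of these alternatives. With a minimum change of 1 log2, 907 genes remained for the γ+ group against control, 868 against the γ- group, and 902 against the 23/24 group. For the γ- group 2 remained against control and 2 against the 23/24 group. Above the 99th percentile limit the first 3 counts were 3577, 3571 and 3598, smaller by construction. For the γ- group against control (696), the count was 436 under median centring, 1363 without a filter, 425 with a filter at the 60th percentile, where fewer genes are tested, 1745 with array weights and 1373 from its 6 arrays alone. For the γ- group against the 23/24 group (812) it was 1641, 488, 2528 and 1760 for no filter, the 60th percentile, array weights and the 6 arrays alone. For the 23/24 group against control (0) it was 1 under quantile normalization and 220 with array weights, which also gave 48 genes called alike in all 3 vector groups. Array weights were lowest for γ+ replicate 2 (0.135) and highest for 23/24 replicate 2 (3.22). Why the other counts moved was not tested. Leaving out each of the 12 arrays gave 6005 to 6682 genes for the γ+ group against control, 5946 to 6641 against the γ- group, 6069 to 6859 against the 23/24 group, 267 to 1665 for the γ- group against control, 0 to 58 for the 23/24 group against control, 263 to 1838 for the γ- against the 23/24 group, 6635 to 7560 for the F test and 0 to 21 for the genes called alike in all 3; the highest value of each came without γ+ replicate 2. List calls numbered 70, 68 to 71 when arrays were left out, and 35 with an estimated correlation. With replicate number as a block the counts were 6401, 514, 0, 6326, 6482 and 628 in the order of the report's 6 comparisons, 6892 for the F test, 0 for the genes called alike in all 3 and 70 for the lists. The numbers did not pair the arrays (18 pairs of equal number, residual r of -0.223 to 0.124; unequal numbers, -0.226 to 0.260). Alternatives for linear values were not run because the range of the values was read as that of log2 intensities.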

Other observations

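Tests of splits were planned; all other tests of explanations in this part were chosen after the calls and largest changes had been seen. The members of several lists moved apart in the γ+ group, and the genes given here were named after their values were seen. Among the G1 cyclins, Ccnd1 fell by 2.06 ± 0.08 log2 (SE, n = 3 per group) while Ccne2 rose from a level of 6.71 to 9.71 and Ccne1 rose by 2.15 ± 0.07. The kinase inhibitor Cdkn1a rose together with all 49 G2/M genes. Among the inflammatory genes, Lcn2 (-1.96 ± 0.08), Ptx3 (-1.82 ± 0.15) and Ccl7 (-1.52 ± 0.06) fell and Tnf (0.95 ± 0.13) and Ccl5 (0.91 ± 0.08) rose. The potassium channel gene Kcnd2 rose from 4.80 ± 0.16 to 6.50 ± 0.16 (SD) while Kcnq1 fell from 8.18 ± 0.10 to 6.16 ± 0.05. These γ+ levels were set across normalization runs.

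Whether the counts of called genes could arise by chance was asked by regrouping the arrays. For 3 against 3 arrays there are 10 splits, too few for a share under 0.05. With the 6 compared arrays alone, the real split called 5964 genes for the γ+ group against control, 1373 for the γ- group against control, 6064 for γ+ against γ-, 6129 for γ+ against 23/24 and 1760 for γ- against 23/24. In each, 1 of the 10 splits, the real one, called as many, and the highest of the others called 0. For the 23/24 group against control the real split called 0 genes, as many or more were called in all 10 splits, and the highest of the others called 1. For the F test, 1 of 100 splits, the real one, called 7045 genes, and the highest of the others called 1. None of the others kept the γ+ arrays together, so in each the γ+ difference entered the spread within groups. The low counts of the other splits may come from that alone. The splits also cannot separate the groups from the normalization runs, so no conclusion on chance is drawn from them.

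The largest pattern was the shift of whole gene lists in the γ+ group, downward for cardiomyocyte genes and upward for cell cycle and interferon genes. Offsets of single probe sets left by a separate normalization would not follow gene function. Yet 11 of the 22 lists had a median outside the whole range of 10000 random lists of matched size and intensity. In the γ- group 2 lists did, and in the 23/24 group 1. For the sarcomere the γ+ median was -1.21 against -0.67 to 0.23. The random lists used the same fold changes as camera and leave out correlation between genes, so they are no separate evidence for the shifts. Oxidative phosphorylation was among the 11, though its limma camera adjusted p was 0.146 with an estimated correlation. A smaller share of cardiomyocytes as the whole cause would raise the markers of other cells. Yet all 4 lists of fibroblast, smooth muscle, endothelial and leukocyte markers had medians below 0 over their 95% intervals. These intervals came from resampling the genes of a list and leave out the spread between arrays. A median below 0 is a weak criterion, because the median of all genes was -0.071. The leukocyte median (-0.378) lay inside the range of its random lists (-0.634 to 0.355), so that list adds little. The fibroblast, smooth muscle and endothelial medians lay below the ranges of theirs. The γ- arrays, also in a run of their own, held 2 genes changed by at least 1 log2 against control, where the γ+ arrays held 907. A response to the γ+ vector remains a hypothesis, and normalization may still contribute to single genes. All γ+ arrays appear to come from a run that holds no other group. Any other difference between the runs that moves whole lists therefore cannot be told apart from the γ+ form.

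The calls in the γ- group against control, and the rise of the skeletal muscle list among them, were the next pattern. Separate normalization is a candidate explanation. Probe sets below the intensity filter, where little RNA is measured, were called more often (10.65%) than those above it (4.92%, 95% interval 4.60 to 5.25%). For the γ+ group, also in its own run, the shares were 23.93% below and 54.81% above. That order is no counterweight, because the γ+ share below the filter was itself larger than that of the γ- group. For the 23/24 group, within the control's run, the shares were 0% and 0.02%. The skeletal list's median of 0.11, not past with an estimated correlation (0.0600), was matched or exceeded in distance from the middle by 110 of 10000 random lists, which is consistent with that explanation but near its limit. In the 23/24 group, within the control's run, the list had a median of 0.07 (limma camera adjusted p = 0.0031, and 0.0641 under quantile normalization). There 1339 of 10000 random lists lay as far from the middle, and both comparisons share the control arrays. Whether part of the γ- shift has another source is therefore open. The interferon and the extracellular matrix and fibroblast lists lay outside the range of their random lists, which offsets unrelated to function would not give. However, the matrix list was not past with an estimated correlation (0.242) and kept 1 of 4 called genes under median centring. That centring moved the median of all genes by 0.016 log2, and under quantile normalization 5 matrix genes were lower. The lost calls alone therefore do not decide the question.

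The rise of interferon and cell cycle genes in the γ+ group was weighed against the virus, because adenovirus can itself induce both. The other vector groups, which also received adenovirus, showed 20.2% (γ-) and 6.8% (23/24) of the γ+ median for interferon. For G1/S they showed 2.8% and -2.3%. The highest upper 95% bound was 24.2%, from resampling list genes with the γ+ median fixed and without the spread between arrays. On these medians the vector itself at an equal dose does not account for most of the rise. The direct comparisons rest on the same group means and are no separate evidence. Their interferon medians were 0.84 above the γ- group and 0.94 above the 23/24 group. More virus in the γ+ cultures cannot be told apart from the γ+ form, as 0 measures of dose are in the labels. All these levels except those of the 23/24 group were set across normalization runs.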
